A study of Mus musculus with 6 samples.

How the data were processed

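RNA sequencing was done on 6 libraries of RAW 264.7 cells, a mouse macrophage line, 3 treated with the solvent DMSO and 3 with bisphenol AP (BPAP). Per the labels' protocols, total RNA was extracted with TRIzol reagent and libraries were made with the VAHTS Universal V6 kit. The dose of BPAP, the exposure time, the strand setting of the library and any selection of poly(A) RNA are not given in the sources used here. Groups were taken from the treatment label of each sample, and replicate numbers from its title.

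The authors deposited 1 table of 34745 genes with a raw count and an FPKM value for each library. Per the submitters' processing notes, HISAT2 version 2.0.4, StringTie version 1.3.3b and edgeR were used with genome build GRCm38, with no role or order given. The counts are whole numbers per gene and per library, per the file headers and the values, and the libraries were not pooled. The deposited FPKM values appear to be computed from the same counts: count divided by FPKM and by the library total gave the same gene length in every library. The largest relative difference of that length between libraries was 8.48e-06 among genes with over 100 counts in every library. This FPKM length is not the length of the gene's exons: it lay within 1% of the summed length of all distinct annotated exons, where a base shared by several exons counts more than once, for 69.2% of the tested genes found in the annotation below, and it exceeded the gene's own span for 750 of them. Exon lengths given here are those of merged exons, each base counted once. The annotation release and the treatment of reads that match several genes are not given in the sources used here. Values of genes with near-identical copies, of overlapping genes and of antisense pairs are therefore uncertain. Coordinates are those of the deposited table. Of its gene identifiers, 34267 were found in the GENCODE M21 annotation, which was used for exon length, GC content and gene type.

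All tests ran on the counts as deposited. A total of 18090 genes had no count in any library. The default expression filter of edgeR left 11711 genes, libraries were scaled by TMM factors, and edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust dispersion estimates, treatment as the only term) compared BPAP with DMSO. P-values are 2-sided with Benjamini-Hochberg adjustment over all genes tested, and the threshold was an adjusted p of 0.05 with no limit on the fold change. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM values are TMM-normalised counts scaled to the library total, and log2 fold changes are BPAP minus DMSO. The common biological coefficient of variation was 0.127. Counts of 11626 genes were simulated with the gene means and library sizes of this comparison and the same dispersion for every gene. The test recovered 50.7% of 67 genes changed 1.5-fold, 91.0% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, with 5 false calls among 165. Far fewer genes were changed there than passed the threshold in the data, so recovery in the data may differ.

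For 36 gene lists fixed before the data were examined, camera (limma 3.58.1) with a preset correlation of 0.01 was run on log2 CPM with a prior count of 2, with adjustment over the 29 lists that had at least 5 tested members. Camera with an estimated correlation and fry were run beside it, and members past the threshold were counted over all genes and adjusted over the list alone. Genes are named by a rule fixed at the same time: the 10 largest rises and the 10 largest falls among genes past the threshold whose BPAP and DMSO values did not overlap, with a mean of at least 100 counts in a group and without predicted genes and pseudogenes; up to 4 members per list with the smallest p among those past the threshold, or 2 where none passed; and 12 macrophage markers. Genes named outside that rule are marked as chosen after their values were seen. A planned test of annotation terms was not run, because the deposited table was used without such terms.

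Library totals ranged from 11084705 to 13806559 counts. A limit of 3 counts corresponds to 0.271 CPM in the smallest library and 0.217 CPM in the largest, without TMM scaling, which covers counting error only. Alternatives were DESeq2 size factors or upper quartile scaling in place of TMM, no filter on low counts, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) of the deposited FPKM values for genes with a mean of at least 1, the replicate number as a block, and each library left out in turn. An alternative chosen after the data were seen removed each library's trend with merged exon length and GC content. That trend was a lowess curve of span 0.3, entered as an offset for the 11665 tested genes with a GC value, and was tested on simulated counts. The same was done with the FPKM length in place of the exon length.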

Results

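Gene expression was measured in RAW 264.7 cells, a mouse macrophage line, after treatment with bisphenol AP (BPAP), an analogue of bisphenol A, or with its solvent DMSO. The series concerns the effect of BPAP on macrophage function in bleomycin-induced lung fibrosis, and the comparison asks which genes differ in macrophages exposed to BPAP. Each group had 3 libraries. Total counts were 11084705, 12550065 and 13806559 in the DMSO libraries and 12427563, 12056332 and 12425350 in the BPAP libraries. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom, between DMSO 2 and DMSO 3, was 7.01.

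In BPAP-treated macrophages, 24 of 36 tested genes of the ATF4 stress response, 18 of 31 antioxidant genes regulated by NRF2, 10 of 19 genes of the proinflammatory activation list and 25 of 46 nuclear genes of the respiratory chain were higher than in DMSO-treated cells, and 21 of 33 G2/M genes and 20 of 38 genes of G1/S and DNA replication were lower. Camera called these lists with a preset correlation, and none with an estimated correlation (adjusted p = 0.412 to 0.560). An alternative chosen after the data were seen removed each library's trend with exon length and GC content. In it, 10 of the 46 respiratory chain genes and 7 of the 19 proinflammatory genes were higher. Cxcl2, which encodes a chemokine that attracts neutrophils, rose 4.02-fold, from 7.85 ± 1.37 to 31.4 ± 7.77 CPM (SD, n = 3 per group). Trib3, a pseudokinase gene induced by ATF4, rose 3.08-fold, from 71.3 ± 12.7 to 220 ± 22.0 CPM. Mki67, a marker of proliferating cells, was 2.65-fold lower, at 408 ± 97.3 against 1081 ± 109 CPM. Lpl, which encodes the lipoprotein-hydrolysing enzyme lipoprotein lipase, was 2.57-fold lower. Mki67 and Lpl are long genes, with merged exons of 10061 and 10478 bases against a median of 4298 for all tested genes. With the exon length and GC trend removed, their log2 fold changes were -1.19 and -1.09. The mitotic genes Ccnb1, Ccnb2, Cdk1 and Cdc20, chosen after their values were seen, did not pass.

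Of 11711 genes tested, 3715 (31.7%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1901 higher and 1814 lower in BPAP. Most changes were small. The median absolute log2 fold change of the genes that passed was 0.52, and 295 of them changed at least 2-fold, 144 higher and 151 lower. The BPAP and DMSO values did not overlap in 5741 genes (49.0%), where chance gives 10%, and 3687 of the genes that passed were among them. Without DMSO 1, 1244 genes were higher. Log2 fold changes fell with gene length. Across genes, which are not independent replicates, their Spearman correlation with the length of the gene's merged exons was -0.40. Each base is counted once in that length.

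Among the 10 largest rises, Car6, a secreted carbonic anhydrase gene (chromosome 4, 150187015 to 150201332, GRCm38), rose 4.00-fold (log2 fold change 2.00, SE 0.14, adjusted p = 0.000106). Acot2, which encodes a mitochondrial acyl-CoA thioesterase, rose 3.33-fold from 7.39 ± 0.24 to 24.7 ± 1.05 CPM (SD, n = 3 per group). Cxcl2 lies on chromosome 5 at 90903871 to 90905938. Chac1, whose product degrades glutathione, rose 3.21-fold, and Cth, whose product makes cysteine from cystathionine, rose 2.94-fold. Tenm4 rose 2.91-fold and Ifitm6, of the interferon-induced transmembrane family, 2.88-fold. Avil rose 3.08-fold and Rnasek 3.18-fold, but Avil overlaps Tsfm on the opposite strand and Rnasek overlaps Gm21988 on the same strand, so their counts are uncertain.

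The largest falls were in Ttc14 (chromosome 3, 33799832 to 33814860), 3.50-fold lower with a log2 fold change of -1.81 (SE 0.20, adjusted p = 0.000722), and in Arhgap33, 3.21-fold lower. Xiap, which encodes a caspase inhibitor, was 3.16-fold lower, at 26.7 ± 1.47 against 84.7 ± 25.9 CPM (SD, n = 3 per group). Polq, the gene of DNA polymerase theta, was 3.04-fold lower, and Kif20b, a kinesin gene of cytokinesis, 2.94-fold lower. The potassium channel gene Kcnd1 was 3.09-fold lower, the incretin receptor gene Gipr 3.04-fold lower and Ccdc18 3.00-fold lower. Ccne2, the gene of cyclin E2, was 3.06-fold lower and Rprd1b 3.07-fold lower, but both overlap a more highly counted gene on the opposite strand, Ints8 and Tgm2. With the exon length and GC trend removed, the log2 fold change of Ttc14, whose merged exons hold 10515 bases, was -1.39.

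**Figure D1:**
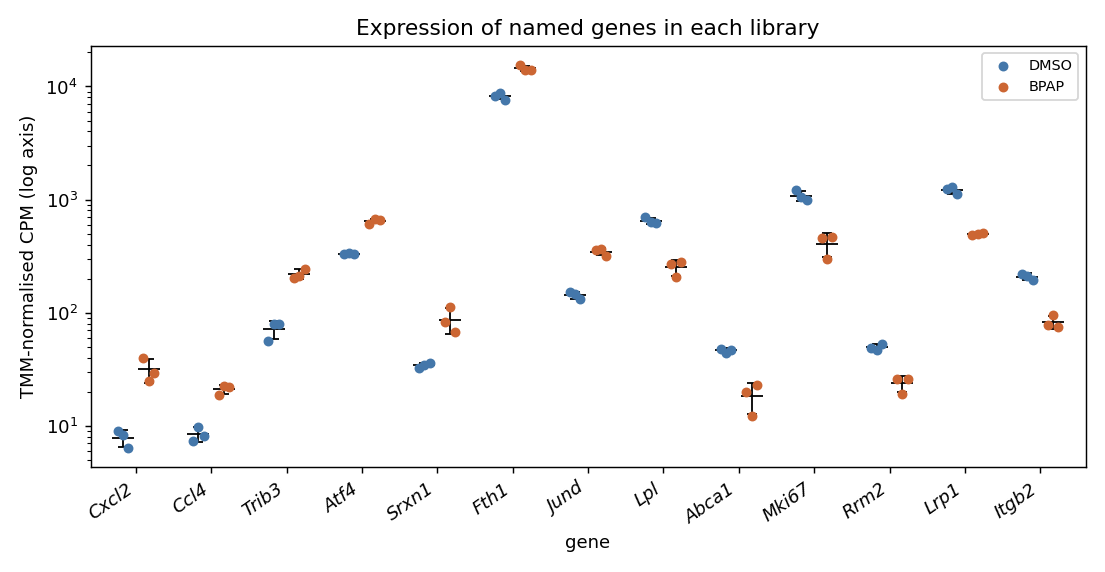
TMM-normalised CPM of 13 named genes on a log axis, with a point for each of the 3 DMSO and 3 BPAP libraries and a black bar for the mean with its SD. The libraries of the groups do not overlap for any gene shown: Cxcl2 to Jund are higher in BPAP, and Lpl to Itgb2 lower.

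Of 36 tested members of the ATF4 integrated stress response list, 24 rose and 0 fell, with a median log2 fold change of 0.50 (camera adjusted p = 2.17e-10). The adjusted p was 0.412 with an estimated correlation, and 30 members were higher when adjusted over the list alone. Atf4 itself, the transcription factor at the head of this response, rose 1.96-fold, from 330 ± 4.97 to 648 ± 30.7 CPM (SD, n = 3 per group). Cebpb, a transcription factor gene, rose 1.84-fold, though it overlaps Tmem189 on the opposite strand. Of 31 NRF2 list members, 18 rose and 0 fell, with a median of 0.49 (camera adjusted p = 9.43e-06). Their adjusted p was 0.412 with an estimated correlation, and the count adjusted over the list alone was also 18. Srxn1, which encodes the peroxiredoxin-repairing enzyme sulfiredoxin, rose 2.53-fold, and Gpx4, which encodes an enzyme that reduces lipid peroxides, 1.88-fold. Fth1, the ferritin heavy chain gene, rose 1.76-fold, from 8209 ± 528 to 14474 ± 852 CPM, and Prdx1 rose 1.70-fold. Hmox1, a fixed marker, rose 1.27-fold (adjusted p = 0.0405), a call lost in every fit without 1 library but that without BPAP 2 (adjusted p 0.0603 to 0.15) and with limma-trend on FPKM (0.0698), and with the exon length and GC trend removed its log2 fold change was 0.07 (adjusted p = 0.687).

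In the proinflammatory activation list, 10 of 19 members rose and 1 fell, with a median log2 fold change of 0.58 (camera adjusted p = 0.00185). The adjusted p was 0.502 with an estimated correlation, and adjusted over the list alone 11 were higher and 1 lower. With the exon length and GC trend removed the median was 0.36 (camera adjusted p = 0.0136, and 0.693 with an estimated correlation). Besides Cxcl2, the chemokine gene Ccl4 rose 2.48-fold, the cytokine subunit gene Il23a 2.98-fold and the siderophore-binding lipocalin gene Lcn2 5.79-fold, the last from only 0.41 ± 0.20 CPM (SD, n = 3). The fixed markers Tnf and Cd86, a cytokine and a costimulatory molecule, rose 1.49-fold and 1.69-fold, and Tnf did not pass with that trend removed (adjusted p = 0.133). Nos2, the gene of inducible nitric oxide synthase, was 1.34-fold lower (log2 fold change -0.42, SE 0.12, adjusted p = 0.0244), and this call was lost without DMSO 1 (adjusted p = 0.0682), without DMSO 2 (0.0972) and without BPAP 3 (0.07). Among immediate early genes, 14 of 24 rose and 0 fell, with a median of 0.54 (camera adjusted p = 0.000286). Their adjusted p was 0.412 with an estimated correlation, and adjusted over the list alone 14 were higher and 1 lower. Without BPAP 2, 2 of them fell. Jund, of the AP-1 transcription factors, rose 2.43-fold, the MAP kinase phosphatase gene Dusp1 2.40-fold, Ier2 1.83-fold and Atf3 1.63-fold.

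The interferon, NF-kB, inflammasome and alternative activation lists were not called, with genes moving both ways. Of 32 type I interferon response genes, 7 rose and 3 fell (camera adjusted p = 0.389), among them Isg15, 4.07-fold higher from 0.91 ± 0.25 CPM (SD, n = 3), Rsad2, 2.79-fold, Oas1g, 1.67-fold, and Bst2, 1.62-fold. With any 1 DMSO library left out or the exon length and GC trend removed, 1 of them fell, and without BPAP 3, 0 fell. In the NF-kB list 5 of 23 members rose and 6 fell (camera adjusted p = 0.786): Slfn2 rose 1.69-fold and Clec4e 1.55-fold, while Rel, an NF-kB subunit gene, was 1.70-fold lower and Tnip3 1.74-fold lower. In the inflammasome list 3 of 15 rose and 2 fell (camera adjusted p = 0.789), with Naip2 1.40-fold and Il18 1.60-fold higher, Aim2 1.26-fold lower and Txnip, which encodes a thioredoxin-binding protein, 2.47-fold lower. The calls of Txnip and Aim2 were lost without DMSO 1 (adjusted p = 0.0577 and 0.0601) and without DMSO 3 (0.0527 and 0.0757), and that of Txnip also without DMSO 2 (0.0602) and BPAP 3 (0.0525), and with no filter on low counts (0.0606). Tnip3 (0.0694) and Il18 (0.0739) did not pass with the exon length and GC trend removed. Of 11 alternative activation genes, Clec10a rose 1.47-fold and the chemokine gene Ccl22 was 2.60-fold lower (camera adjusted p = 0.884). The list's median log2 fold change was 0.05, its mean -0.13 and its test direction down, and over the fits without 1 library the median ranged from -0.10 without BPAP 1 to 0.06 without BPAP 2. The fixed markers Il10 and Ccl2 had 0 counts in all libraries, which allows up to 0.271 CPM in the smallest library, and Arg1, Il6, Il1b and Mrc1 were below the filter, with at most 2, 3, 4 and 14 counts in a library.

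**Figure D2:**
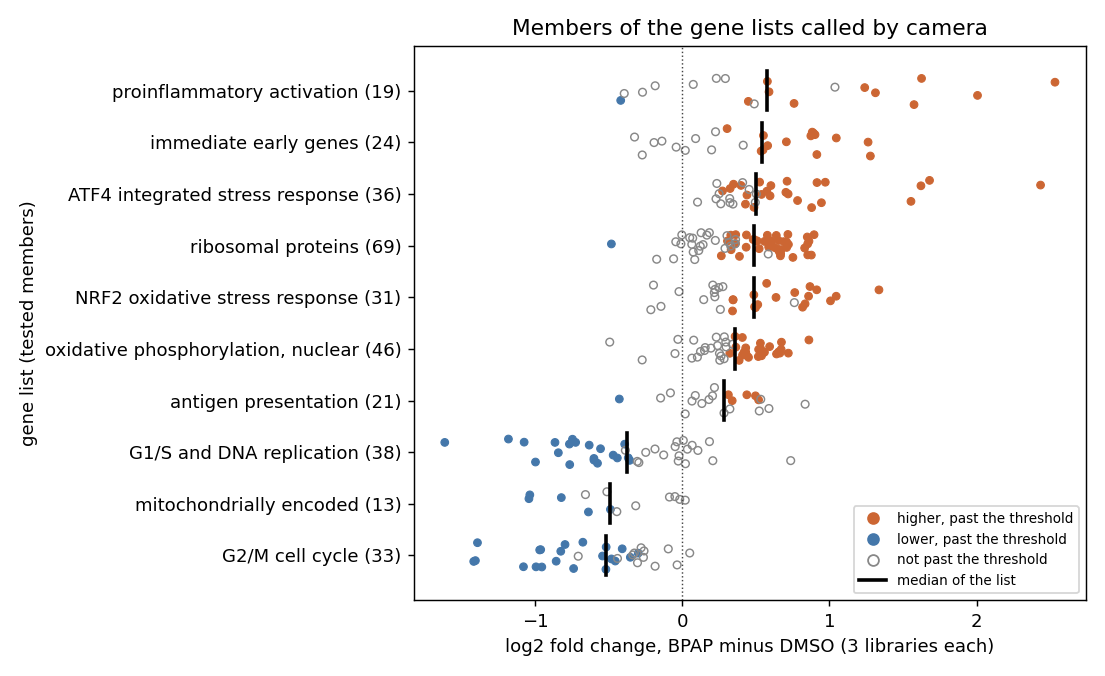
Log2 fold change (BPAP minus DMSO) of each tested member of the 10 gene lists called by camera. Filled points passed the threshold, open points did not, and the black bar is the list's median, which ranges from -0.52 for G2/M genes to 0.58 for proinflammatory genes.

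In the G2/M cell cycle list 21 of 33 members were lower and 0 higher, with a median log2 fold change of -0.52 (camera adjusted p = 9.57e-09). The adjusted p was 0.560 with an estimated correlation, and 28 members were lower when adjusted over the list alone. Besides Mki67, Ttk, a spindle checkpoint kinase gene, was 1.99-fold lower, Anln, of the contractile ring, 1.94-fold lower and Ect2, a cytokinesis gene, 1.77-fold lower. Chosen after their values were seen, the mitotic genes Ccnb1, Ccnb2, Cdk1 and Cdc20 did not pass, with log2 fold changes of -0.03, -0.09, 0.05 and -0.18. Of 38 G1/S and DNA replication genes, 20 fell and 0 rose, with a median of -0.38 (camera adjusted p = 6.38e-06). Their adjusted p was 0.412 with an estimated correlation, and adjusted over the list alone 21 were lower and 1 higher. Without DMSO 2 or without BPAP 1, 13 of them fell. Pola1, the gene of the catalytic subunit of DNA polymerase alpha, was 2.27-fold lower, Rrm2, of ribonucleotide reductase, 2.10-fold lower, the kinase gene Cdc7 2.00-fold lower and Uhrf1 1.82-fold lower. After removal of the exon length and GC trend, 26 G2/M and 19 G1/S genes were lower. Of the replication-dependent histones, 4 were tested and 0 passed at an adjusted p of 0.05, Hist1h1c at a log2 fold change of 0.42 (adjusted p = 0.289) and Hist1h2bc at -0.40 (adjusted p = 0.306). Without BPAP 2, Hist1h1c passed at 0.69 (adjusted p = 0.000461).

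Ribosomal protein genes rose together with nuclear genes of the respiratory chain, and both lists hold short genes, with median merged exon lengths of 2007 and 1918 bases against 4298 for all tested genes. Of 69 ribosomal protein genes, 44 rose and 1 fell, with a median log2 fold change of 0.49 (camera adjusted p = 4.58e-11). The adjusted p was 0.412 with an estimated correlation, and adjusted over the list alone 48 were higher and 1 lower. Rps28 rose 1.86-fold, Rplp1 1.82-fold, Rpl19 1.57-fold and Rpl31 1.5-fold. Genes whose symbols start with Rpl or Rps took 3.61 ± 0.11% of the counts in DMSO and 5.01 ± 0.33% in BPAP (SD, n = 3 per group, 2-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Of 46 nuclear respiratory chain genes, 25 rose and 0 fell, with a median of 0.36 (camera adjusted p = 1.57e-07). Their adjusted p was 0.412 with an estimated correlation, and adjusted over the list alone 31 were higher and 1 lower. Cox5b rose 1.65-fold, Atp5c1 1.60-fold, Cox4i1 1.58-fold and Cox6a1 1.43-fold. With the exon length and GC trend removed, the list medians were 0.27 and 0.17 (camera adjusted p = 3.77e-05 and 0.0153, and 0.594 and 0.693 with an estimated correlation), 29 ribosomal protein and 10 respiratory chain genes were higher, and Cox6a1 did not pass (adjusted p = 0.134). Of 13 mitochondrially encoded genes, 5 fell and 0 rose, with a median of -0.49 (camera adjusted p = 0.0246). The adjusted p was 0.767 with an estimated correlation, and 6 were lower when adjusted over the list alone. mt-Cytb was 1.77-fold lower, while mt-Nd4 was 2.06-fold lower, mt-Nd4l 2.05-fold lower and mt-Atp8 1.55-fold lower. These last 3 genes overlap neighbours on the same strand and lost their calls without BPAP 2 (adjusted p = 0.116, 0.143 and 0.175) and without BPAP 3 (0.0644, 0.0774 and 0.0912), and mt-Nd4l and mt-Atp8 also without BPAP 1 (0.0671 and 0.0646). With no filter on low counts all 3 lost their calls (0.0724, 0.0901 and 0.0863), and 1 gene of the list fell. Mitochondrial genes took 10.8% of the counts in DMSO 1, 7.02% and 7.35% in the other DMSO libraries and 6.53% to 7.55% in the BPAP libraries. The list was not called without DMSO 1 (median -0.23, adjusted p = 0.0534), without BPAP 2 (0.0527) or without BPAP 3 (0.0610), and 1 gene passed without either of those BPAP libraries and 2 without BPAP 1.

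**Figure D3:**
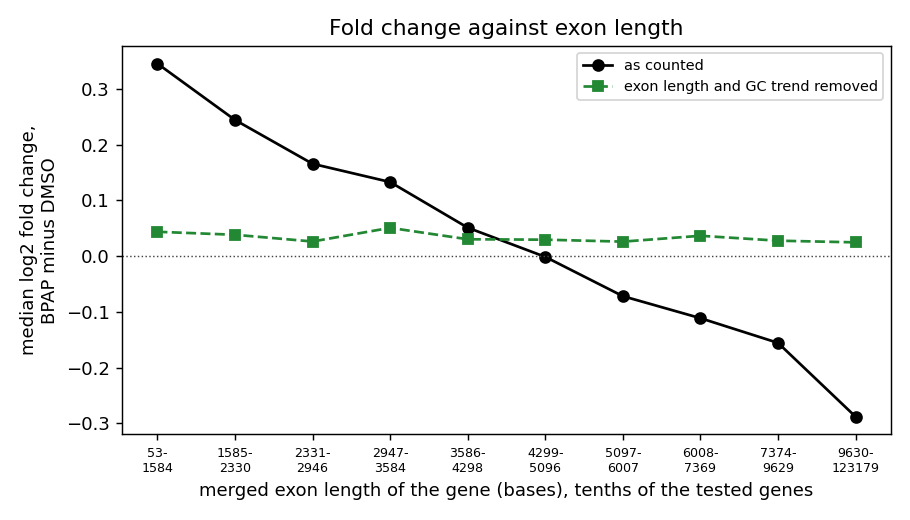
Median log2 fold change (BPAP minus DMSO) in deciles of the tested genes by merged exon length in bases, as counted (black circles) and with each library's exon length and GC trend removed (green squares). The median falls from 0.35 in the shortest decile to -0.29 in the longest, and lies between 0.02 and 0.05 in every decile after removal.

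In the shortest decile of the tested genes, 428 were higher and 44 lower in BPAP, and in the longest decile 29 were higher and 513 lower. Each library's deviation from the gene means had a Spearman correlation with exon length, across genes, of 0.32 to 0.33 in the DMSO libraries and -0.35 to -0.31 in the BPAP libraries (2-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). These deviations were from the means over all 6 libraries and cancel out for each gene, so the signs of the groups are not independent. With the exon length and GC trend removed, 2735 genes passed at an adjusted p of 0.05, 1557 higher and 1178 lower. Of the 3715 genes 2130 were among them, 2128 in the same direction. Ankrd17 and Hook3, chosen after their values were seen, turned from log2 fold changes of -0.28 and -0.43 to 0.28 and 0.27.

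Lipid genes and surface receptors moved both ways. Of 14 LXR target and sterol efflux genes 3 rose and 3 fell (camera adjusted p = 0.855): Plin2, which coats lipid droplets, rose 1.67-fold and Smpdl3a 1.72-fold, while the cholesterol exporter gene Abca1 was 2.55-fold lower, at 18.2 ± 5.49 against 46.3 ± 1.93 CPM (SD, n = 3 per group), and Rab7b 1.54-fold lower. Without BPAP 2, 6 of these genes fell. Of 32 fatty acid metabolism genes 7 rose and 3 fell (camera adjusted p = 0.425), with Hilpda 1.70-fold, Eci1 1.65-fold and Ech1 1.43-fold higher and Lpl lower, and without DMSO 3, 1 fell. In the cholesterol synthesis list 6 of 26 rose and 2 fell (camera adjusted p = 0.115), with Sc5d 1.44-fold and Mvd 1.34-fold higher and Idi1 1.45-fold lower. Cyp51 was 1.40-fold higher but overlaps Akap9 on the opposite strand. Without DMSO 1, 2 of these genes rose, and without DMSO 3, 3 rose, while the list was called without DMSO 2 (adjusted p = 0.0493) and without BPAP 3 (0.0369). The adjusted p in these fits was 0.779 and 0.715 with an estimated correlation. Mvd lost its call without DMSO 1 (adjusted p = 0.0630) or DMSO 3 (0.0577) and with the exon length and GC trend removed (0.114). Among 23 phagocytic and scavenger receptors 4 rose and 3 fell (camera adjusted p = 0.786): the Fc receptor genes Fcgr1 and Fcgr4 rose 2.35-fold and 1.5-fold, the endocytic receptor gene Lrp1 was 2.43-fold lower and Itgb2, the beta chain of leukocyte integrins, 2.53-fold lower. Of 17 chemokine receptor and adhesion genes 2 rose and 2 fell (camera adjusted p = 0.642), with Itgb5 1.53-fold and Ccr1 2.70-fold higher. Csf1r, the receptor gene for macrophage colony-stimulating factor, was 1.33-fold lower, and Cx3cr1, which shares its locus with Csrnp1, Gorasp1, Xirp1 and Wdr48, 2.04-fold lower. The call of Ccr1 was lost without DMSO 1 (adjusted p = 0.0630) and DMSO 3 (0.0548) and with DESeq2 (0.0504), and that of Csf1r without DMSO 2 (0.0520) and BPAP 1 (0.0502).

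Among 20 fibrosis-associated mediators 6 rose and 1 fell (camera adjusted p = 0.0769). Lgals3, the galectin 3 gene, rose 1.71-fold, the urokinase receptor gene Plaur 2.15-fold, the cytokine gene Osm 1.76-fold and the lipid carrier gene Fabp5 1.5-fold. Tgfb1, a fixed marker, did not pass, at 142 ± 10.4 against 129 ± 24.4 CPM (SD, n = 3 per group) and a log2 fold change of 0.14 (SE 0.13, adjusted p = 0.445). Spp1, the osteopontin gene, rose 1.24-fold (adjusted p = 0.0368), a call lost in every fit without 1 library but that without BPAP 2 (adjusted p 0.0503 to 0.143), with limma-trend on FPKM (0.0567) and with the exon length and GC trend removed (0.354). Without BPAP 3 and with limma-trend on FPKM the list was called (adjusted p = 0.0400 and 0.0364, and 0.547 and 0.550 with an estimated correlation). Of 38 lysosome genes 9 rose and 3 fell (camera adjusted p = 0.0769), with the protease genes Ctsd and Ctsl 1.86-fold and 1.52-fold higher, Cd63 1.66-fold and Npc2 1.37-fold. With no filter on low counts this list was called (adjusted p = 0.0437, and 0.417 with an estimated correlation). In the antigen presentation list 5 of 21 rose and 1 fell, with a median log2 fold change of 0.28 (camera adjusted p = 0.0349). The adjusted p was 0.516 with an estimated correlation, and adjusted over the list alone the counts were also 5 and 1. H2-Q6 rose 1.41-fold, H2-D1 1.36-fold and Psmb8 1.27-fold, and Nlrc5, a regulator of MHC class I genes, was 1.34-fold lower. This list was not called without DMSO 1 (adjusted p = 0.0534), DMSO 3 (0.0540, median 0.18) or BPAP 2 (0.0527), nor with the exon length and GC trend removed (median 0.08, adjusted p = 0.685, 2 higher and 2 lower), and 3 members rose without DMSO 2, BPAP 1 or BPAP 3. Psmb8 lost its call without DMSO 1 (0.0826), DMSO 3 (0.0598) or BPAP 3 (0.0517), and with the trend removed (0.0760).

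Of 23 endoplasmic reticulum chaperones 5 rose and 3 fell (camera adjusted p = 0.678): Sec61b, of the translocon, rose 1.94-fold, Derl1 1.78-fold and Dnajb9 1.42-fold, and the calreticulin gene Calr was 1.56-fold lower. Without BPAP 3, 6 of them fell, and 5 with the exon length and GC trend removed. In the cytosolic heat shock list 4 of 17 rose and 0 fell at an adjusted p of 0.05 (camera adjusted p = 0.123), Dnajb1 2.27-fold, Hspe1 1.47-fold, Fkbp4 1.38-fold and Ahsa1 1.35-fold, but Hspe1 overlaps the more highly counted Hspd1 on the opposite strand. Fkbp4 did not pass without DMSO 1 (adjusted p = 0.0564). Of 21 p53 targets 7 rose and 3 fell (camera adjusted p = 0.425), with Gadd45a 2.03-fold and the pro-apoptotic gene Bax 1.58-fold higher and Gtse1 and Ckap2 1.5-fold and 1.55-fold lower. Without any 1 of DMSO 1, DMSO 2, DMSO 3 or BPAP 2, 4 of them rose. Among 29 glycolysis and hypoxia genes 3 rose and 6 fell (camera adjusted p = 0.642), Tpi1 1.38-fold and Higd1a 1.42-fold higher and Kdm3a and Adm 1.61-fold and 1.62-fold lower. Fewer fell without DMSO 2 or DMSO 3 (3 each) and without BPAP 1 (2). Of 10 nuclear receptors, Esrra was 1.41-fold higher and Rara 1.41-fold lower (camera adjusted p = 0.727), but Esrra did not pass without DMSO 1 (0.163), DMSO 3 (0.0898) or BPAP 2 (0.12), with the exon length and GC trend removed (0.0690) or with limma-trend on FPKM (0.0789), nor Rara without DMSO 2 (0.0516). Of 13 osteoclast genes, Jdp2 was 1.82-fold higher and Mitf 1.43-fold lower (camera adjusted p = 0.786). Ugt1a6a, which shares exons with other Ugt1a genes, was the only 1 of 5 AHR targets that passed, at 1.93-fold higher (camera adjusted p = 0.786), and this list's median log2 fold change was 0.12 with a mean of -0.35. Over the fits without 1 library that median ranged from -0.12 without BPAP 1 to 0.37 without DMSO 1. The call of Ugt1a6a was lost without DMSO 2 (0.0747), DMSO 3 (0.0844), BPAP 2 (0.0582) or BPAP 3 (0.0721). The mean and the median, or the test direction, also differed in sign for the NF-kB, inflammasome and osteoclast lists. Adjusted over the list alone, the counts differed from those over all genes for the cholesterol (7 higher, 2 lower), p53 (8 and 3), glycolysis (3 and 7) and nuclear receptor (0 and 1) lists among the lists that camera did not call.

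Of 12 macrophage identity genes 6 rose and 1 fell (camera adjusted p = 0.130), with Lyz2 1.28-fold and Cebpa 1.47-fold higher. Without DMSO 1, DMSO 2 or DMSO 3, 3 of them rose, and without BPAP 1, 2 rose. Cebpa did not pass without DMSO 1 (adjusted p = 0.0791), DMSO 2 (0.0878) or BPAP 1 (0.0608). With the exon length and GC trend removed 1 member rose and 2 fell, and neither Cebpa (0.10) nor Lyz2 (0.554) passed. Fibroblast, epithelial and neutrophil markers had 0 genes past the filter, and the highest of them, the collagen gene Col1a1, had means of 0.346 CPM in DMSO and 0.271 CPM in BPAP, here without TMM scaling. Of the T and NK cell markers Lck was tested and rose 1.62-fold, from 4.84 ± 0.59 to 7.87 ± 1.26 CPM (SD, n = 3 per group), a call lost without DMSO 1 (adjusted p = 0.0642) or DMSO 3 (0.0559). Of the B cell markers Ighm, the immunoglobulin heavy chain mu gene, was tested and was 1.77-fold lower, at 91.6 ± 9.64 against 162 ± 15.1 CPM. The dendritic cell marker Zbtb46 did not pass, at a log2 fold change of -0.26 (SE 0.45, adjusted p = 0.685). Of the genes named above, Txnip, Gadd45a, Csf1r, Tpi1, Cox4i1, Esrra, Rpl31 and Rps28 also overlap a gene of lower count on the opposite strand, and Spp1 one on the same strand, so reads may have been counted for either.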

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

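The tests with a length and GC trend removed were chosen after the data were seen, the others before. The number of genes past the threshold was 3733 with DESeq2 size factors, 3780 with upper quartile scaling, 3690 with no filter on low counts, 3612 with DESeq2, 3730 with limma-voom, 3463 with limma-trend on log2(FPKM + 1) and 2735 with the exon length and GC trend removed, against 3715. In that last fit 1178 genes were lower, against 1814; the cause was not tested. With the FPKM length in its place 3028 genes passed, 2383 of them among the 3715 and all of these in the same direction; the heat shock list was then called (adjusted p = 0.0296, and 0.643 with an estimated correlation), and Ahsa1, Bax, Higd1a and Idi1 also lost their calls (0.0888, 0.0886, 0.0862 and 0.0659). The number was 1663 at an adjusted p under 0.01, and 337 at an unadjusted p under 0.05 with at least 2-fold. Genes higher in BPAP ranged from 1244 to 1654 over the fits without 1 library, the lowest without DMSO 1, and all genes past the threshold from 2511 to 3314; these fits have fewer libraries. At least 2-fold, 95 genes passed with limma-trend on log2(FPKM + 1), against 295. That fit differs in test, scaling, pseudocount and genes kept, and which of these lowers the number was not tested. With an estimated correlation 0 lists were called, against 10. Fry, which does not compare a list with other genes, called 12: 7 of the 10, without G2/M (adjusted p = 0.0535), antigen presentation (0.0581) and mitochondrially encoded genes (0.229), and 5 others. The 5 were the lysosome and cytosolic heat shock (0.0095 each), fatty acid metabolism (0.0129), fibrosis-associated mediator (0.0221) and macrophage identity (0.0432) lists, with test direction up. With the exon length and GC trend removed, fry did not call macrophage identity (0.716). Apart from Ankrd17 and Hook3 with the exon length and GC trend removed, no gene or list named here changed direction with a call. The NRF2 median was 0.31 with limma-trend on FPKM, against 0.49. Of the named genes, 11 lost their call with the exon length and GC trend removed, and 5 to 12 without any 1 library. Same-numbered libraries deviated from their group means with correlations of 0.10, 0.05 and 0.01, not all over 0.1, so the numbers were not taken to pair the samples. These small positive values do not exclude a pairing, which stays open. DMSO 1 and DMSO 2 correlated best with the BPAP library of their own number, and DMSO 3 with BPAP 2; with the replicate block 4236 genes passed, and of the named genes Txnip did not (adjusted p = 0.0641). Alternatives planned for tables of normalized values alone did not apply, and annotation terms were not tested. Depth limits genes of low count: Il10 and Ccl2 at 0 counts could each lie up to 0.271 CPM in the smallest library. Changes of 1.5-fold were recovered in 50.7% of 67 simulated genes, a share not examined by depth or count.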

Other observations

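The tests of symbol families, those with a length and GC trend removed and those of an explanation as the whole cause were chosen after the data were seen. Gene families beyond the fixed lists also moved. Grouped by the stem of their symbols, 125 families were tested in both directions (1-sided Fisher's exact test, Benjamini-Hochberg adjustment over 250 tests). This test takes genes as independent, which members of a family measured in the same libraries are not. Its p-values do not measure the spread between libraries. Besides the cytosolic ribosome's own Rpl and Rps genes, 25 of 48 Mrpl genes and 16 of 29 Mrps genes, of the mitochondrial ribosome, rose and 0 fell (adjusted p = 2.50e-06 and 0.000113). Of 13 Timm genes, of the mitochondrial import machinery, 9 were higher and 1 lower (adjusted p = 0.00106), and 7 of 10 Psmb genes, of the proteasome core, were higher and 0 lower (adjusted p = 0.00489). Among families that fell, 17 of 30 Kif genes, the kinesin motors, and 18 of 33 Cep genes, of the centrosome, were lower (adjusted p = 2.28e-05 for each), and 1 Kif gene was higher. Also lower were 8 of 10 Dock genes (adjusted p = 0.000476) and 10 of 17 Kdm genes, the histone demethylases (adjusted p = 0.00166).

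Of the 19 family calls, 6 were also made with the exon length and GC trend removed. Among them were 12 of 29 Mrps and 16 of 48 Mrpl genes higher (adjusted p = 0.0199 and 0.0264) and 13 of 30 Kif and 10 of 33 Cep genes lower (adjusted p = 0.000414 and 0.0295). The calls of Psmb (5 of 10, adjusted p = 0.138), Timm (4 of 13, adjusted p = 0.699), Dock (4 of 10, adjusted p = 0.162) and Kdm (3 of 17, adjusted p = 1) were lost. Dock and Kdm genes had median merged exon lengths of 11797 and 8225 bases. The Mcm helicase genes were enriched among lower genes after removal (6 of 10, adjusted p = 0.0105) and not before (5 of 10, adjusted p = 0.143). Also called only after removal were Eif genes (17 of 52 higher, 3 lower, adjusted p = 0.0264) and Sec genes (10 of 24 higher, 2 lower, adjusted p = 0.0295). The same held for Ccdc genes (17 of 79 lower, 5 higher, adjusted p = 0.0337).

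BPAP 2 lay apart from BPAP 1 and BPAP 3 on the second principal component (22.7 against -14.6 and -18.0), so each list below was also tested without it. Ribosomal protein genes (median log2 fold change 0.49) and nuclear respiratory chain genes (0.36) had medians of 0.27 and 0.17 with the exon length and GC trend removed, 54.0% and 47.9% of the medians as counted, with camera adjusted p of 3.77e-05 and 0.0153 (0.594 and 0.693 with an estimated correlation). With the FPKM length in place of exon length the medians were 0.26 and 0.22, or 52.2% and 62.0%, with camera adjusted p of 9.35e-07 and 0.00133 (0.643 and 0.647 with an estimated correlation). With bootstrap SE of 0.036 to 0.052, part of each median remained after removal of the trend with either length. The criterion for a whole cause was set after these medians were known, so it could not test that explanation. How much of the change the trend accounts for stays open. Both lengths draw on all annotated exons of a gene, so a trend with the length of the expressed transcripts was not tested. Here and below, the bootstrap SE takes the genes of a list as units, not the libraries, so it does not measure the spread between libraries. Without BPAP 2 the medians were 0.46 and 0.31, which argues against that library as the source. The correlation with exon length had the same sign in all 3 DMSO libraries and the opposite sign in all 3 BPAP libraries. The opposite signs follow in part from the use of deviations from the mean of all libraries, and do not show which group holds the trend. A difference in RNA integrity or library preparation between the groups, which may accompany treatment or not, cannot be told apart from BPAP here.

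The rise of ATF4 genes (median 0.50) was 0.45 with the exon length and GC trend removed, 0.47 with the FPKM length in its place and 0.48 without BPAP 2. These values argue against either trend, as fitted over all genes, or that library as the main cause. Within the ATF4 list, the Spearman correlation of log2 fold change with exon length was -0.65 as counted and -0.26 after removal. A length effect stronger in its members than over all genes stays open. NRF2 genes (median 0.49) had 0.41 with the FPKM length and GC trend removed, which argues against that trend as the main cause. They had 0.35, or 72.8%, with the exon length and GC trend removed (camera adjusted p = 0.000464, and 0.594 with an estimated correlation). The share of this trend stays open, since this median lies within its bootstrap SE (0.119) of 50%. Without BPAP 2 the NRF2 median was 0.33, 67.8% of that with all libraries (camera adjusted p = 3.88e-05, and 0.504 with an estimated correlation). Part of the rise was thus present without this library, and how much more than the others it contributes stays open. For NRF2 genes too, the criteria for a whole cause were set after these values were known, so they could not test it. No biological explanation was tested for either list.

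The fall of G2/M genes (median -0.52) and of G1/S genes (median -0.38) was -0.51 and -0.34 with the exon length and GC trend removed, -0.48 and -0.37 with the FPKM length in its place, and -0.35 and -0.36 without BPAP 2. These values argue against either trend, as fitted over all genes, or that library as the main cause. For G2/M genes without BPAP 2 the margin was narrow (bootstrap SE 0.078), so how much more that library contributes than the others stays open. Within the G2/M list, across genes, the Spearman correlation of log2 fold change with exon length was -0.70 as counted and -0.45 with the exon length and GC trend removed. It was -0.65 and -0.26 in the ATF4 list and -0.62 and -0.50 in the proinflammatory list. The refit thus did not fully remove the relation with length within these lists. A length effect stronger in their members than over all genes stays open. The G2/M members Ccnb1, Ccnb2, Cdk1 and Cdc20, chosen after their values were seen, did not pass, at log2 fold changes of -0.03, -0.09, 0.05 and -0.18. No biological explanation was tested.

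The 6 libraries can be split into 3 and 3 in 10 ways. The real split gave 3715 genes past the threshold and the highest of the others 1, so 1 of 10 splits gave as many. With so few splits no share under 0.05 can be reached.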
